A study of Mus musculus with 5 samples.

How the data were processed

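The libraries were made with the 10x Genomics 5′ high-throughput kit from live CD45+ cells sorted from 9 samples of 3 mice (tumour, tumour-draining and non-draining lymph node), per the series' design text. The deposited table holds counts of unique molecular identifiers (UMIs), whole numbers per feature and cell with no normalization. It was made by the authors with Cell Ranger 8.0.1, per the submitters' processing notes, from 4 gene expression libraries and 1 hashtag library of 1 pool, and holds called cells only. Reads were aligned to mm10-1.2.0, per the series' design text, and cells under 500 UMIs, under 200 genes or over 20% mitochondrial counts were to be removed. Whether intron reads were counted is not given in the sources used here. The 5 deposited libraries are not biological samples: the 9 samples are told apart only by hashtag.

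The table has 21624 barcodes, 27998 genes, 9 features of antibody capture and 9 of multiplexing capture. No barcode was under 500 UMIs, 15 were under 200 genes and 90 over 20% mitochondrial, and the 93 barcodes failing any of these were removed here, which left 21531 cells with 128285378 UMIs (medians 3973 UMIs and 1664 genes, 1.65% mitochondrial). A cell was given to a hashtag where its antibody capture count was at least 3 times that of the next, which left 258 cells without one and 21273 with one. The top hashtag held a median of 93.7% of a cell's hashtag UMIs. The labels name the tags as TotalSeq-C and the table as TotalSeq-B, and neither says which tag belongs to which mouse and site, so the hashtag populations were numbered 1 to 9 by tag and left unassigned. Comparisons of tumour with lymph node and of the antibodies, which had been planned, were not run.

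In populations 1 to 9, in order, total gene UMIs came to 15122204, 9247030, 9202501, 22233399, 10407648, 9233709, 31330079, 10454929 and 10129975, and median UMIs per cell to 5683, 3377, 3682, 7198, 3460, 3565, 10660, 3415 and 3612. Intervals are 95%, exact Poisson (a conditional binomial for ratios) or exact Clopper-Pearson, and cover counting error only. A count of 0 was taken to allow up to 3 counts.

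Clustering used scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, python-igraph 0.11.9, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 under Python 3.11.15, and figures matplotlib 3.10.9. Doublets were called with Scrublet at an expected 8% (211 cells, 0.98%, removed) and none by hashtag, which left 21320 cells, 21070 of them with a hashtag. The other 250 stay in all pooled shares and levels, and in no population. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen and the genes of the result lists removed from them (1947 left), values were scaled with a limit of 10, and 30 principal components and 15 neighbours fed Leiden clustering at resolution 1.0, which gave 24 clusters. A cluster was named "X-like" from 27 marker classes (135 markers, 129 of them in the table) where the mean log2 fold of a class's markers over the other cells was at least 2 (prior 5 CPM), at least 3 markers were in at least 5% of cells, and the next class lay at least 0.4 lower. A cluster in which another class reached 5 stayed unnamed whatever its other values. Of the others, clusters with median UMIs under 0.75 of their own samples' and Malat1 over 2 times that of the pool were set apart. The marker lists and the result lists were chosen before the data were examined, together with the comparisons, the alternatives and the rule for naming genes. The naming thresholds and the Malat1 rule were set after the clusters had been seen.

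The 11 result lists hold 95 genes, all present in the table: PD-1 and its ligands, inhibitory receptors and exhaustion, costimulatory receptors, cytotoxic effectors and cytokines, stem-like and memory genes, Fc gamma receptors, interferon response, MHC class II presentation, microvillus and contact proteins, proximal T cell receptor signalling, and immediate early and heat shock genes. They were written from general knowledge of the field. Gene positions are from GENCODE vM21 (GRCm38). Levels are counts summed over a class's cells per 1000000 UMIs (CPM). A ratio was read only where both classes together had at least 50 UMIs, and a gene was counted as higher or lower where the ratio was at least 2 or at most 0.5 and its interval left out 1. Populations were compared within themselves where they held at least 20 cells of both classes. Each list's median log2 ratio was set against 10000 random lists of other genes matched on expression. For macrophages against monocytes the median log2 was -0.70 for PD-1 and its ligands (percentile 0.22 among the random lists), -0.67 for the interferon list (0.05), -0.52 for the immediate early (0.29), -0.41 for the inhibitory (0.89), -0.38 for the contact (1.22) and -0.20 for the costimulatory list (10). It was -0.034 for the T cell receptor list (31.1), 0.05 for the Fc (39.5), 0.10 for the stem-like (59.3), 0.20 for the cytotoxic (61.3) and 0.45 for the MHC class II list (99.3).

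The rule for naming genes took, in each comparison, the 10 list genes with the largest ratio in each direction among those with at least 50 UMIs and an interval that left out 1, and Pdcd1, Cd274, Pdcd1lg2 and the Fc receptor genes where a class held at least 20 UMIs. Some genes that this rule took are not reported here, and none was put in their place. Examples beyond it in the text were chosen after their values were seen. Shares of cells with a UMI were taken after thinning each cell at random to 1500 UMIs, leaving out shallower cells (18 activated CD8 T-like, 71 Treg-like and 329 B cell-like). The split of activated CD8 T-like cells by Pdcd1 used the same thinned counts. Migratory DC-like cells were to be compared with type 2 conventional DCs, but no cluster could be named as these, so macrophages took their place after the data had been seen, and a comparison of the unnamed cluster 14 with naive CD8 T-like cells was added in the same way.

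The rules were tested on simulated data in which counts of the real classes were drawn from 1 profile and chosen genes changed. For activated CD8 T, Treg and macrophage cells against their partners, 0 of 67, 5 of 67 and 1 of 67 genes changed 1.5-fold were called, 67, 66 and 66 of 67 changed 4-fold, and 66, 66 and 65 of 66 changed 8-fold, none in the wrong direction. Of 9854, 9721 and 10750 unchanged genes 9, 20 and 15 were called, and the interval held the true ratio in 95.7, 95.5 and 95.4%. A list raised at least 4-fold came out above all random lists in each, and 12, 13 and 6 of 200 unchanged lists fell outside the middle 95%. Class totals were drawn as Poisson counts, with no spread between cells, mice or populations. Coverage near 95% and few false calls were therefore set in advance, and how the rules fare under real spread was not tested.

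Alternatives were Leiden resolutions of 0.6 and 1.6, no doublet removal, stricter filters of 1000 UMIs, 500 genes and 10% mitochondrial, list genes kept in the clustering, the mean over cells in place of summed counts, and thinning to 1000 UMIs or none. Added after the data had been seen were shared populations only, Treg-like cells with a Foxp3 UMI only, activated CD8 T-like cells joined with the Malat1-high cluster 13, 20 other draws of the thinning, and leaving out each population in turn.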

Results

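RNA of single mouse immune cells was counted in 21531 cells that passed the stated filters, taken from 3 mice and, in each mouse, from the tumour, a lymph node draining it and a distant lymph node. Each mouse had received 1 antibody: the PD-1 blocking antibody nivolumab as a mouse IgG1 with the D265A exchange in its Fc part, nivolumab as a mouse IgG1 without it, or the isotype control MOPC21. Cells of the 9 samples carried sample-specific hashtag antibodies and were run as 1 pool. The deposited table names the hashtags by number only, and nothing in the sources used here ties a number to a mouse or a site. The samples are therefore called populations 1 to 9, in the order of the hashtag numbers, and tumours were not compared with lymph nodes, nor antibodies with each other. No antibody has a replicate mouse and the unassigned populations are no replicates of a group, so no test was run, and every interval (95%, exact Poisson for levels and ratios, exact Clopper-Pearson for shares) covers counting error only. After filtering the populations held 2056 to 2581 cells (median 2375), 9202501 to 31330079 gene transcripts counted by unique molecular identifier (UMI; median 10407648), and medians of 3377 to 10660 UMIs per cell.

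B cell-like cells made up 28.7% of the 21320 cells left after doublet removal (95% interval 28.1 to 29.3%). Naive T cells followed, with 14.2% naive CD4 T-like (13.7 to 14.6%) and 12.4% naive CD8 T-like cells (11.9 to 12.8%), the circulating cells that have not met antigen. Among cells that act in inflamed tissue, macrophage-like cells made up 7.97% (7.61 to 8.34%), activated CD8 T-like cells, led by Cxcr6, Ifng, Gzmk and Lag3, 5.06% (4.77 to 5.36%), and monocyte-like cells, led by Chil3 and Hp, 4.28% (4.01 to 4.56%). Regulatory T (Treg)-like cells, led by Foxp3, Tnfrsf4 and Izumo1r, made up 4.41% (4.14 to 4.69%) and natural killer (NK)-like cells 2.96% (2.74 to 3.20%). Rarer classes were cycling cells with 1.56% (1.40 to 1.73%), migratory dendritic cell (DC)-like cells, led by Fscn1 and Ccl22, with 0.858% (0.739 to 0.992%), germinal centre B-like cells with 0.732% (0.622 to 0.855%), and plasmacytoid DC-like cells with 0.117% (0.0759 to 0.173%). Clusters with low UMI counts and high Malat1, a nuclear transcript, held 9.46% of cells, and 7.34% stayed unnamed.

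The 9 populations differed widely in these shares. In populations 1 to 9, in order, B cell-like cells made up 0.439, 45.7, 25.6, 0.479, 58.5, 33.4, 0.244, 53.1 and 37.7%. Naive CD4 T-like cells made up 0.292, 17.8, 29.5, 0.174, 11.2, 27.4, 0.0406, 14.8 and 25.3%. Activated CD8 T-like cells, whose perforin and granzymes kill target cells, made up 29.3, 0.256, 0.0438, 13.5, 0.0848, 0.128, 5.64, 0.209 and 0.196%. Macrophage-like cells, which take up dead cells, made up 10.6, 0.256, 0.263, 19.6, 0.212, 0.299, 39.6, 0.377 and 0.275%. These shares leave out the unnamed cluster 10, whose macrophage markers fell short of the limit for a name (mean log2 1.81). It held 204, 225 and 32 cells of populations 1, 4 and 7. Monocyte-like cells ranged from 0.0848 to 19.8% (median 0.219%) and NK-like cells from 0.209 to 13.02% (median 0.470%). Treg-like cells, which restrain other T cells, ranged only from 1.91 to 6.74% (median 4.41%). Germinal centre B-like cells, in which antibody genes mutate, ranged from 0 to 2.88%, and a count of 0 in populations 1, 4 and 7 allows up to 0.146, 0.131 and 0.122%. The macrophage and monocyte shares were unstable: clustered anew with the 211 called doublets kept in, they came to 9.63% and 1.18% of all cells. Those 211 cells are too few to account for the fall in monocytes, so the border between the clusters was redrawn. Clustering resolution moved others by more than 1.5-fold: macrophages came to 12.7% at the coarser resolution and Treg-like cells to 1.88% at the finer one, and migratory DC-like cells came to 0.535% with list genes kept in the clustering.

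**Figure D1:**
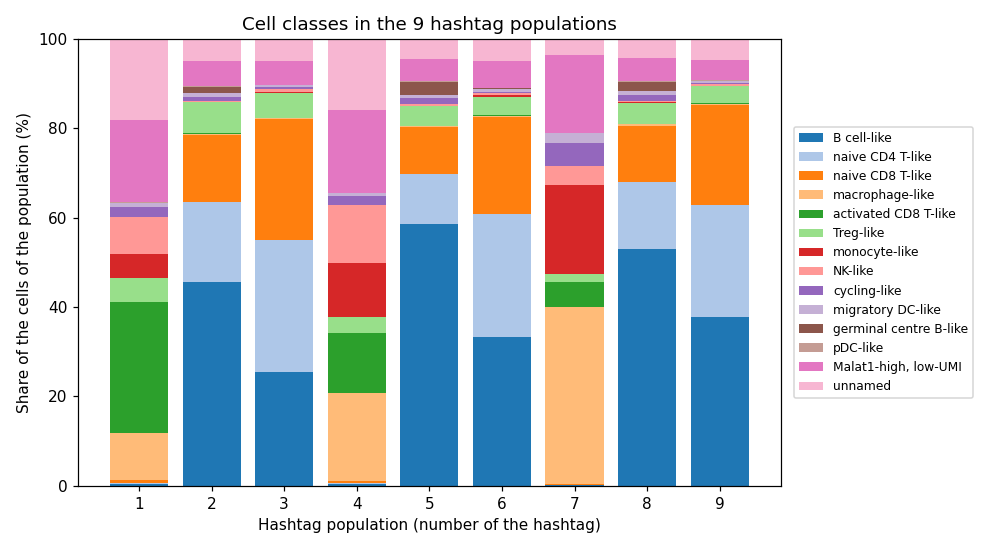
Stacked bars give the share of cells (%) of each cell class in populations 1 to 9 after doublet removal. Activated CD8 T-like cells make up 29.3, 13.5 and 5.64% of populations 1, 4 and 7.

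PD-1 (mouse Pdcd1, ENSMUSG00000026285, chromosome 1, 94038305 to 94052553 in GRCm38), an inhibitory receptor on T cells, was highest in activated CD8 T-like cells, at 532 counts per 1000000 UMIs (CPM; 516 to 549). Treg-like cells followed at 94.0 CPM (85.2 to 104) and NK-like cells had 20.7 CPM (16.3 to 25.8), while B cells, macrophages, monocytes and naive T cells had 2.29 to 4.79 CPM. With every cell thinned to 1500 UMIs, 48.6% of activated CD8 T-like cells held a Pdcd1 UMI (45.5 to 51.6%; 86.4% unthinned, median depth 6716 UMIs). This draw of the thinning lay low: the expected share was 51.4%, and 20 other draws gave 49.3 to 53.9%. B cells, a class that should hold almost none, gave 0.432% (0.2796 to 0.637%; 0.801% unthinned, median depth 3020 UMIs), against 12.9% in Treg-like cells (10.7 to 15.3%; 23.5% unthinned, median depth 3992 UMIs). In populations 1, 4 and 7 the activated CD8 T-like cells held 551, 527 and 489 CPM of Pdcd1.

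The ligand PD-L1 (Cd274, ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), which myeloid cells raise under interferon, was highest over all populations in monocyte-like cells (406 CPM, 393 to 419) and migratory DC-like cells (405 CPM, 373 to 439). In population 7, the only one with at least 20 cells of both, it had 271 CPM in monocytes (257 to 285) and 393 in migratory DC-like cells (343 to 448), which had 142 (83.9 to 224) in population 2 and 351 (264 to 458) in population 8. Macrophage-like cells followed with 250 CPM (244 to 256), B cells with 131 and Treg-like cells with 113, while naive CD4 T-like cells had 43.9 CPM. The other ligand, PD-L2 (Pdcd1lg2, ENSMUSG00000016498, chromosome 19, 29410919 to 29471161), which DCs and macrophages are known to carry, reached 85.3 CPM in migratory DC-like cells (71.1 to 102). It had 85.0 CPM in NK-like cells (76.0 to 94.9), reached 69.3 CPM in activated CD8 T-like cells (63.6 to 75.5) and 55.4 CPM in Treg-like cells (48.7 to 62.8), and stood at 10.9 CPM in macrophages. These levels pool different samples: within population 7, migratory DC-like cells had 103 CPM of Pdcd1lg2 (78.8 to 133) and NK-like cells 60.0 (42.1 to 83.1), whereas migratory DC-like cells of populations 2 and 8 had 7.87 and 6.51 CPM from 1 UMI each. Cd86, the costimulatory ligand on antigen-presenting cells, was highest over all populations in migratory DC-like cells (486 CPM) and monocytes (465 CPM). In population 7 it had 545.5 and 440 CPM in these, but migratory DC-like cells of populations 2 and 8 had 346 and 273. Cd80, a ligand of CD28 and CTLA-4 that also binds PD-L1, reached 110 CPM in migratory DC-like cells and 42.4 CPM in monocytes. Cd274 in migratory DC-like cells came to 644 CPM with list genes kept in the clustering.

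**Figure D2:**
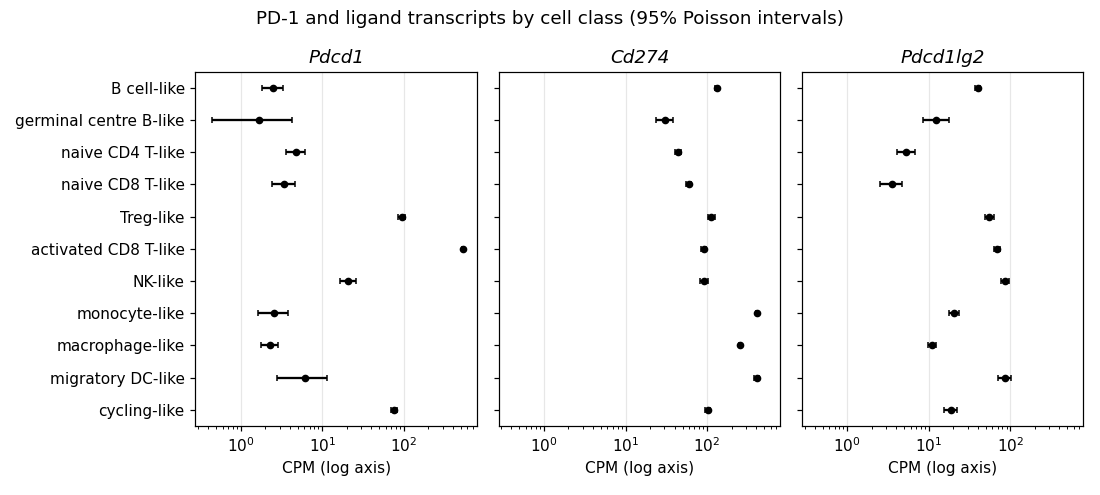
Levels of Pdcd1, Cd274 and Pdcd1lg2 in 11 cell classes, in counts per 1000000 UMIs (CPM) on a log axis, with 95% exact Poisson intervals. Pdcd1 is highest in activated CD8 T-like cells (532 CPM), Cd274 in monocyte-like (406 CPM) and migratory DC-like cells (405 CPM).

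Fc gamma receptors, through which the Fc part of an antibody engages a cell and which the D265A exchange is meant to escape, were concentrated in macrophages and monocytes. The shared signalling chain Fcer1g had 5535 CPM in macrophages, 4308 in monocytes and 2495 in NK-like cells. Of the activating receptors, Fcgr4 had 741 CPM in macrophages (732 to 751) and 584 in monocytes, Fcgr1 had 589 and 716, and Fcgr3 had 693 and 820, with 83.2 CPM of Fcgr3 in NK-like cells. The inhibitory receptor Fcgr2b had 632 CPM in macrophages, 892 in monocytes and 132 in B cells. In activated CD8 T-like cells Fcgr1, Fcgr2b, Fcgr3 and Fcgr4 stood at 4.83 to 8.23 CPM, within 2-fold of naive CD8 T-like cells. MHC class II transcripts, which present peptides to CD4 T cells, were led by Cd74 in macrophages (30175 CPM) and B cells (29168 CPM).

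Activated CD8 T-like cells had 45 of 93 measured list genes at least 2-fold higher than naive CD8 T-like cells and 11 lower, by size and not by a test. Without population 1, 39 were higher and 10 lower. All 10 measured cytotoxic and cytokine genes were higher, with a median log2 ratio of 6.90: Gzmk was 216-fold higher (128 to 395), Gzmb 181-fold (159 to 208), Ccl4 173-fold (154 to 195), Ccl3 150-fold (123 to 186), Gzma 102-fold (84.1 to 125; 31.0-fold without population 4 and 186-fold without population 1) and Ifng 140-fold (110 to 179). Inhibitory receptors, which mark chronically stimulated T cells, were higher in 9 of 12 genes (median log2 3.35), with Lag3 190-fold (147 to 249) and Havcr2 75.5-fold higher (58.1 to 100), while Btla was 4.57-fold lower (3.31 to 6.44). Of 7 genes of PD-1 and its ligands 4 were higher: Pdcd1 156-fold (115 to 218), Cd80 28.2-fold, Pdcd1lg2 19.8-fold (14.5 to 27.9) and Cd86 3.40-fold. Cd274 was 1.53-fold higher (1.38 to 1.70), inside the 2-fold limit. Costimulatory receptors were higher in 4 of 6 genes, among them Tnfrsf9 (47.9-fold, 42.0 to 54.9), which signals survival, and Cd226 (2.11-fold, but 1.77-fold without population 1).

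Genes of resting and stem-like T cells were lower in 7 of 8 (median log2 -3.98). S1pr1, the receptor that lets T cells leave tissue, was 46.4-fold lower (33.7 to 65.7), Tcf7, the transcription factor of stem-like cells, 32.5-fold (26.4 to 40.3), Klf2 19.6-fold (17.9 to 21.5) and Id3 19.4-fold (12.6 to 31.5). Cxcr5, the follicle homing receptor, was 12.8-fold (4.16 to 63.5), Slamf6 6.23-fold (4.99 to 7.88) and the interleukin 7 receptor Il7r 2.30-fold lower (2.16 to 2.45). In activated CD8 T-like cells Cxcr5 had 3 UMIs in population 1 and 0 in populations 4 and 7. Its 5.93-fold without population 1 takes 3 counts for a count of 0, so it is a lower limit. Among the microvillus and contact proteins, 6 of 12 were higher and none lower: the adhesion genes Cd44 (8.68-fold), Itgb2 (3.85-fold), Cd48 (3.62-fold) and Itgal (3.02-fold) led, while the microvillus linkers Ezr, Rdx and Msn stayed within 2-fold. Interferon response genes were higher in 6 of 10, led by Ifit3 (8.69-fold) and Isg15 (8.03-fold), which came to 4.60-fold and 4.41-fold without population 1, with Cxcl10 and Irf7 then at 1.57-fold and 1.42-fold. Of 8 genes of proximal T cell receptor signalling only Zap70 was at least 2-fold higher (2.40-fold), and of 9 immediate early and heat shock genes 5 were higher and Fos was 2.04-fold lower. Of the 5, Nr4a1 lay at the limit (2.001-fold) and was under it with any 1 of 7 populations left out. The heat shock genes Hspa1b (18.5-fold) and Hspa1a (15.1-fold) rested on population 1, with 1.56-fold and 1.82-fold without it, and Fos was 1.83-fold lower without it. No MHC class II gene was higher, H2-DMa was 2.29-fold lower, and of the Fc receptor genes only Fcgrt was apart (11.8-fold lower, 5.54 to 29.8; 6.38-fold without population 1 and 19.4-fold without population 4). The medians of the cytotoxic and inhibitory lists lay above all 10000 random lists of genes of like expression, and genes are not independent replicates. No test was run, and no population held 20 cells of both classes, so class and sample cannot be told apart in this comparison.

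Treg-like cells had 38 of 90 measured list genes at least 2-fold higher than naive CD4 T-like cells and 2 lower, by size and not by a test. Il2 had the largest ratio (below), followed by receptors of activated Tregs: Tnfrsf9 was 43.3-fold higher (37.1 to 50.7), Tnfrsf4 40.7-fold (36.0 to 46.2), Tigit 39.5-fold (32.9 to 47.7) and Lag3 32.1-fold (23.6 to 44.8; 19.6-fold without population 1). Ctla4, the receptor through which Tregs remove CD80 and CD86, was 10.3-fold higher (9.71 to 11). Within the 6 populations that hold at least 20 cells of both classes these folds were smaller, at 9.03 to 30.01 for Tnfrsf9, 16.6 to 38.1 for Tnfrsf4, 10.1 to 33.9 for Tigit and 3.70 to 18.6 for Lag3. The pooled values also hold Treg-like cells of the other populations. Of 11 inhibitory receptor genes 10 were higher (median log2 3.25), although Btla (2.06-fold) was 1.90 to 1.96-fold without population 2, 3, 5 or 8, and of 7 genes of PD-1 and its ligands 6, among them Pdcd1 (19.6-fold, 14.9 to 26.3), Cd80 (18.0-fold, 9.77 to 36.4), Pdcd1lg2 (10.5-fold, 7.93 to 14.03) and Cd274 (2.57-fold, 2.27 to 2.91). Cd80 rested on 79 UMIs against 12, and was 1.09-fold higher in population 9 and 25.02-fold in population 2. Klf2 (3.70-fold, 3.51 to 3.90) and S1pr1 (3.44-fold, 3.12 to 3.79), which keep naive T cells circulating, were the 2 lower genes. Jun (1.94-fold), Tcf7 (1.72-fold), Il7r (1.46-fold), Dnajb1 (1.32-fold), Ezr (1.19-fold), Irf1 (1.16-fold) and Msn (1.12-fold) were lower by less, and Irf1 turned higher at the finer clustering and in Treg-like cells with a Foxp3 UMI. Cxcr5, the receptor that draws T cells to follicles, was 11.8-fold (7.99 to 17.9) and the T cell growth factor Il2 235-fold higher (79.4 to 1145), the latter at 58.1 CPM against 0.248 from 3 UMIs, and 463-fold without population 9.

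Contact proteins were higher in 4 of 12 genes, with Cd44 at 7.99-fold and Icam1 at 3.77-fold, costimulatory receptors in 3 of 6 and interferon response genes in 2 of 10, Cxcl10 (7.36-fold) and Isg15 (2.96-fold). Ptpn22 alone of 8 receptor signalling genes (2.09-fold, 1.996-fold without population 1) and Fosb alone of 7 immediate early genes (4.41-fold) were higher, and none of 5 measured Fc receptor and 5 MHC class II genes was apart. Cytotoxic and cytokine genes were higher in 8 of 11 (median log2 2.78), among them Gzmb (22.6-fold, 19.7 to 26.1), Ifng (10.9-fold, 7.72 to 15.7) and Ccl4 (9.08-fold). Without population 4, Gzmb was 14.9-fold, Ccl4 4.05-fold and Ccl3 3.60-fold higher. No test was run, but in the 6 populations with both classes 33 of the 38 higher and both lower genes kept their direction in each, and with these populations alone 32 of the 38 were still at least 2-fold higher. Of the 8 higher cytotoxic and cytokine genes 4 did not: within those 6 the ratio of Gzmb was 0.405 to 7.06, of Ccl4 0.698 to 5.89 and of Ccl3 0.238 to 2.99 (median 0.938), and Gzma came to 1.92-fold without population 4, against 5.41-fold pooled. Pdcd1 was 5.07 to 36.8-fold higher. A finer clustering placed 390 cells of the class among Treg-like and 370 among activated CD4 T-like cells. Il2 was then 15.6-fold (9.41 to 27.8) and Cxcr5 2.12-fold (1.46 to 3.11) higher in activated CD4 T-like cells, which held 2.35 CPM of Foxp3, than in Treg-like cells, which held 284. These still had 8.39 CPM of Il2 (4.80 to 13.6) and 23.6 of Cxcr5 (17.2 to 31.6), against 0.248 and 2.64 in naive CD4 T-like cells.

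Macrophage-like and monocyte-like cells, successive stages of the myeloid cells that enter inflamed tissue, differed in few list genes at the 2-fold limit: of 91 measured genes 2 were at least 2-fold higher in macrophages, 8 lower and 81 neither, by size and not by a test. Nr4a1, an immediate early gene and regulator of monocytes, was 5.64-fold lower in macrophages (5.36 to 5.94), Cd80 5.19-fold (4.41 to 6.11), Btla 3.95-fold (2.29 to 6.87), Tnfrsf9 2.87-fold, Cd101 2.75-fold, Id3 2.47-fold and Cd44 2.07-fold. Cd86 (1.99-fold) and Egr1 (1.93-fold) came just short of 2-fold. Cd274 was 1.62-fold (1.56 to 1.69) and Pdcd1lg2 1.86-fold lower (1.55 to 2.23) in macrophages, inside the 2-fold limit. Of 10 interferon response genes only Isg15 passed 2-fold, at 2.06-fold lower, but the list median log2 ratio was -0.67, and that of PD-1 and its ligands -0.70. Fcgrt, the receptor that recycles IgG, was 2.14-fold higher in macrophages (1.92 to 2.38) and Gzmc 2.11-fold (1.41 to 3.27), while the MHC class II list had a median log2 of 0.45 with H2-Eb1 1.66-fold, Cd74 1.54-fold and H2-Ab1 1.39-fold higher. Spn (1.92-fold), Ifng (1.76-fold), Ccl4 (1.68-fold), Tnfrsf4 (1.67-fold) and Klf2 (1.39-fold) were higher in macrophages by less than 2-fold. Fcgr2b was 1.41-fold and Fcgr1 1.22-fold and Fcgr3 1.18-fold lower in macrophages, and Fcgr4 1.27-fold and Fcer1g 1.28-fold higher. Without population 4, Gzmc was 1.52-fold higher, Ifng 1.07-fold higher and Pdcd1lg2 2.86-fold lower, and without population 7 Isg15 was 1.93-fold lower, Id3 3.85-fold lower and Ifng 2.69-fold higher, with 1 and 5 genes at least 2-fold higher. In each of populations 1, 4 and 7, which hold at least 20 cells of both, all 8 lower genes and Fcgrt kept their direction. Gzmc did not: it stood at 3.16, 11.1 and 4.66 CPM in macrophages of these populations against 5.93, 2.94 and 2.52 in monocytes. At the finer resolution and with list genes kept in the clustering, 0 genes were at least 2-fold higher in macrophages. No test was run, and the border between the classes shifted when cells were clustered anew without doublet removal. Then 10 genes were higher and 32 lower, Pdcd1lg2, Fcgr1, Fcgr2b, Fcgr3, Cd101 and Tnfrsf9 were higher in macrophages, and Gzmc, Spn, Ifng, Tnfrsf4 and Klf2 lower.

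Migratory DC-like cells, which carry antigen to lymph nodes, had 29 of 90 measured list genes at least 2-fold higher than macrophage-like cells and 18 lower, by size and not by a test. Btla was 70.2-fold higher (45.0 to 113), the costimulatory ligand Cd80 13.4-fold (10.9 to 16.4), Tnfrsf4 12.1-fold (8.96 to 16.2) and Pdcd1lg2 7.79-fold (6.29 to 9.61), while Cd274 was 1.62-fold higher (1.49 to 1.76). Tnfrsf9 (7.47-fold), Lag3 (4.80-fold), Nr4a1 (4.77-fold), Gzma (4.34-fold), Tox (4.23-fold) and Tcf7 (4.06-fold) were higher too, but Gzma and Nr4a1 were lower with list genes kept in the clustering, and Gzma at the finer resolution and, by 3.69-fold, without population 7. Ifng (2.08-fold higher in the pool) was 1.83-fold lower without population 7 as well. Fc receptors were lower in 5 of 6 genes (median log2 -2.67): Fcgr3 11.1-fold (9.07 to 13.8), Fcgr2b 8.64-fold (7.16 to 10.5), Fcgr4 7.76-fold (6.58 to 9.23), Fcer1g 5.21-fold (4.96 to 5.48) and Fcgr1 4.62-fold (4.00 to 5.37), whereas Fcgrt stayed within 2-fold. The chemokines Ccl4 (6.61-fold) and Ccl3 (5.66-fold), which draw T cells and monocytes, were lower as well, as were Vsir (4.17-fold), Itgal (3.46-fold) and Entpd1 (3.03-fold). Costimulatory receptors were higher in 5 of 6 genes, and T cell receptor signalling genes in 5 of 8, although the median of the latter was -0.014 within population 7, and without it Lck (1.72-fold), Zap70 (1.85-fold) and Lat (1.96-fold) were inside the 2-fold limit. Several T cell genes rested on few UMIs. In population 7, 51 migratory DC-like cells held 6 of Lag3, 5 of Tox, 8 of Tcf7 and 12 of Lck. The 976 macrophages there held 81, 30, 43 and 99, and were deeper (median 18726 against 9725 UMIs). Free RNA and doublets were not tested for these genes. No test was run. Population 7 alone held at least 20 cells of both, and there 28 of the 29 higher and 17 of the 18 lower genes had the same direction, but only 19 and 14 of them were still at least 2-fold apart. Sizes differed there: Btla was 122-fold, Pdcd1lg2 22.5-fold, Gzma 12.4-fold and Cd274 2.17-fold higher, and Ccl4 had 0.3501, Fcgr1 0.340, Fcgr4 0.227 and Itgal 0.581 of the macrophage level. Without population 7 Pdcd1lg2 was 3.51-fold higher (13.9-fold without population 4), Btla 40.2-fold and Tcf7 2.65-fold (2.48-fold without population 8), and Ccl4 was 18.7-fold, Fcgr4 14.05-fold, Itgal 7.62-fold and Fcgr1 7.25-fold lower, with 21 genes higher and 19 lower.

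Among activated CD8 T-like cells thinned to 1500 UMIs, 515 of 1060 held a Pdcd1 UMI, and none of 73 measured list genes was at least 2-fold apart between cells with and without one. The chemokine Ccl4 was 1.64-fold, Fasl, which kills through Fas, 1.32-fold, the early gene Fos 1.31-fold, Ccl3 1.28-fold, Nr4a1 1.23-fold and Junb 1.12-fold higher with a Pdcd1 UMI. Ctla4 was 1.21-fold (1.08 to 1.35) and Prf1 1.13-fold higher (1.008 to 1.27), H2-Eb1 stood at 0.642 and the integrin Itgb2 at 0.857 of the level without one. Medians over 20 other draws of the thinning lay nearer 1 for all of them. They were 1.25 for Ccl4, 1.16 for Fasl and Ccl3, 1.10 for Nr4a1, 1.06 for Ctla4 and 1.04 for Prf1. Junb came to 1.03, Fos to 1.004, H2-Eb1 to 0.818 and Itgb2 to 0.982 (0.8805 to 1.159 over the draws). The share with a UMI was 49.3, 48.0 and 46.3% in populations 1, 4 and 7. No test was run, and of these genes only Fasl, joined by Ptpn6, stayed above 1 in all 20 other random draws of the thinning, in which at most 1 gene was at least 2-fold higher and at most 1 lower. Cells of 1 common profile in a simulation gave 56.2% with a UMI (51.4% expected over draws of the real cells) and likewise no gene 2-fold apart. That simulation held no gene that truly differed, so how large a real difference the split could show is not known.

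**Figure D3:**
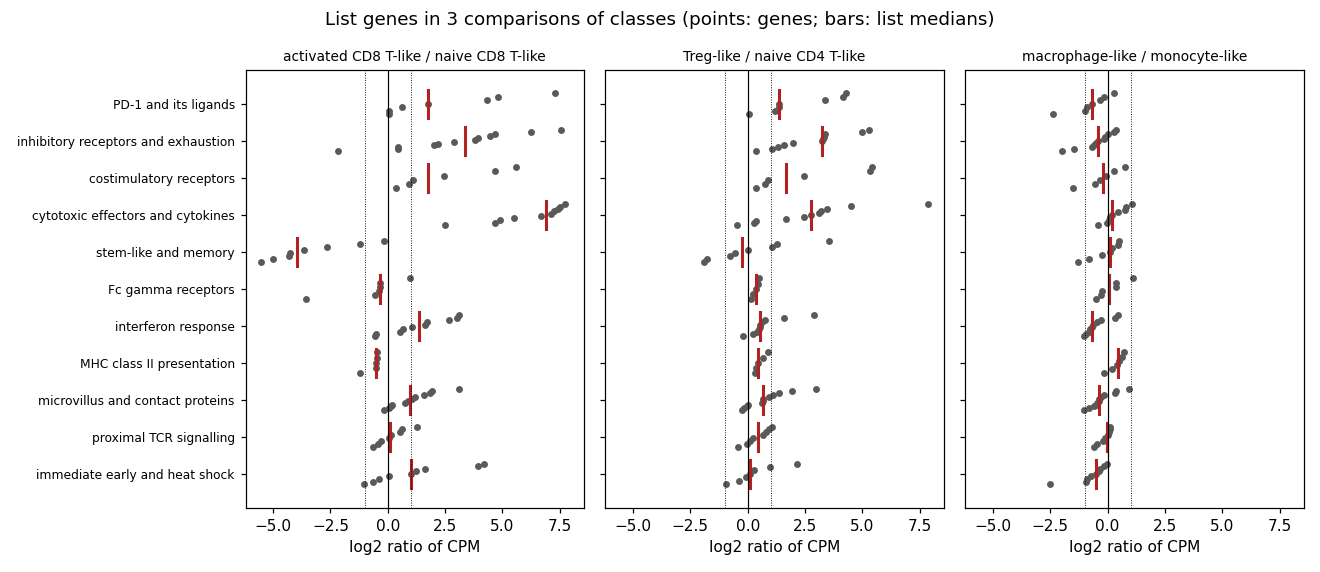
Each point is the log2 ratio of the CPM of 1 list gene between the classes named above the panel, with gene lists along the axis, red bars at list medians and dotted lines at 2-fold. In the activated CD8 T panel the cytotoxic list has a median of 6.90 and the stem-like list -3.98.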

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

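Of the tests here, both of free RNA, the finer clustering of the Treg-like class, the ribosomal share of shallow cells, the comparison with every named cluster, the gene spans and the run-on from Cd274 were chosen only after the result was seen.

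The table holds 37370056 UMIs in 9 multiplexing capture features that no comparison uses. They stand beside 35305304 UMIs in the 9 antibody capture features, a ratio of 1.06, and the top hashtag is the same in both for all 21624 barcodes. No biological explanation applies to them and none was tested.

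PD-L2 (Pdcd1lg2), known from DCs and macrophages, stood at 69.3 CPM in activated CD8 T-like and 85.0 CPM in NK-like cells, against 10.9 CPM in macrophages. In populations 1, 4 and 7 activated CD8 T-like cells had 69.2, 74.4 and 59.2 CPM and NK-like cells 75.0, 100 and 60.0, against 8.83, 26.4 and 4.61 in macrophages. Free RNA would add a like number of UMIs to each cell, so CPM alone cannot decide. Macrophages were deeper, with medians of 15360 to 18726 UMIs against 4174 to 7983. In population 7, 83 UMIs fell in 976 macrophages, 71 in 139 activated CD8 T-like and 36 in 106 NK-like cells. In population 1 these were 28 in 217, 284 in 600 and 69 in 173, and both argue against free RNA. In population 4, 205 in 451, 167 in 310 and 203 in 299 lay closer. The 9 samples were run as 1 pool, so free RNA would add a like number of UMIs per cell in every population. The 83 UMIs in 976 macrophages of population 7 therefore argue against free RNA as the source in population 4 as well. Doublets with migratory DCs would bring Fscn1 and Ccl22, the higher of which reached 0.200% of the level such doublets would need. Transcripts running on from the neighbouring Cd274, 22.8 kb away, would keep the ratio to Cd274 alike, yet there were 0.763 Pdcd1lg2 UMIs per Cd274 UMI in activated CD8 T-like cells (0.680 to 0.855) and 0.0502 in monocytes (0.0432 to 0.0581). Intron reads within the 60.2 kb gene and the antisense gene that overlaps it stay open, and no biological explanation was tested.

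Clusters 3, 5, 11 and 13, with 414, 351, 969 and 283 cells, had 17148, 16596, 21078 and 17942 CPM of the nuclear RNA Malat1, against 8528, 7444, 5135 and 5182 in partners set by hand: B cell-like, Treg-like with naive CD4 T-like, macrophage-like with monocyte-like, and activated CD8 T-like cells. The markers of cluster 11 matched type 1 conventional DCs best (mean log2 1.23), of which no cluster was named, and those of cluster 13 Tregs (1.49) before activated CD8 T cells (1.23), so these partners are open. Shallow capture of whole cells would leave the mix of RNAs as it is, but partner cells with no more UMIs than the cluster's median had at least 2.63 times its ribosomal protein share (1.69 times for cluster 13 against Treg-like cells, and at least 1.49 times against any named cluster with at least 20 such cells), while their Malat1 levels had left this open. The profile is consistent with loss of RNA outside the nucleus, since the ribosomal protein share was 5.98, 4.49, 3.23 and 4.54% against 21.8, 24.5, 10.2 and 16.2%, a ratio of at least 3.16, and at least 1.53 against each of the 15 named clusters. It is also consistent with intron reads of long genes among the counts, since the genes higher in each cluster had a median span at least 8.56 times that of the lower genes, and at least 3.41 times against each named cluster. Both may hold at once, and these values do not tell damaged cells apart from nuclei, nor was a biological explanation tested. The mitochondrial share, also of RNA outside the nucleus, was higher in each cluster. It was 2.425, 2.782, 3.665 and 2.517% against 2.055, 1.592, 1.033 and 0.9487% in the partners. These mitochondrial values argue against loss of all RNA outside the nucleus, as in bare nuclei, while loss of a part of it, as in damaged cells, stays open.

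Il2 and Cxcr5, genes of activated and follicular helper CD4 T cells, the first of which Tregs are known to repress, were 235-fold and 11.8-fold higher in the Treg-like class than in naive CD4 T-like cells. Free RNA would put Il2 in naive cells as well, where its upper counting bound was 0.724 CPM against 58.1 in the class. A candidate explanation for a part of this is CD4 T cells without Foxp3 in the same cluster: the finer clustering placed 390 of its 940 cells among 400 Treg-like cells with 284 CPM of Foxp3, 370 among 374 activated CD4 T-like cells with 2.35, and the others elsewhere, and both genes were at least 2.12-fold higher in the latter. It leaves much open, since the finer Treg-like cells still held 23.6 CPM of Cxcr5 (17.2 to 31.6) and 8.39 of Il2 (4.80 to 13.6), against 2.64 and 0.248 in naive CD4 T-like cells. Within the undivided class, 39 UMIs of Il2 fell in the 709 thinned cells without a Foxp3 UMI and 0 in the 160 with one, while Cxcr5 was 1.30-fold higher without one (0.606 to 3.18), which left it open. Pdcd1 stood at 1.08-fold in the finer Treg-like cells over the activated CD4 T-like cells (0.884 to 1.32), Gzmb at 56.1-fold and Tnfrsf9 at 16.4-fold.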

How the results depend on the processing

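Of the settings below, shared populations, Treg-like cells with a Foxp3 UMI, the joined activated CD8 T class, the other draws and leaving out each population were chosen after seeing the data, and the comparisons of migratory DCs with macrophages and of cluster 14 were added then as well. Of 145 shares, levels and counts under an alternative, 106 stayed within their limits, 39 moved and 0 reversed. Of 1104 single genes and list medians, 779 stayed, 297 moved and 28 reversed. All values below are under the alternative and the cause was not tested for any of them.

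At resolution 0.6 the share of Treg-like cells was 5.71%, of activated CD8 T 6.58% and of macrophages 12.7%, and Pdcd1 in activated CD8 T was 503 CPM.

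At resolution 1.6 shares were 27.8% for B cells, 1.88% for Tregs, 2.16% for cycling cells, 6.77% for macrophages, 0.661% for migratory DCs and 12.3% for naive CD4 T. Cd274 was 468 CPM in migratory DCs and 390 in monocytes, and Pdcd1 119 in Tregs. Macrophages against monocytes had 0 genes higher and 14 lower. Irf1 in Tregs reversed to 0.064, Ifng in macrophages to -0.20 and Gzma in migratory DCs to -0.52 (log2).

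In Treg-like cells with a Foxp3 UMI, Irf1 reversed to 0.052 (log2). In shared populations, 4 genes were lower in Tregs and Fcer1g reversed to -0.035, cluster 14 had 15 higher and 4 lower, with Cd274 at -0.24 and the interferon list median at -0.39, and the T cell receptor list median of migratory DCs was -0.014 (log2).

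With list genes kept in the clustering, the share of migratory DCs was 0.535%, Cd274 was 644 CPM in them and 388 in monocytes, macrophages against monocytes had 0 higher and 13 lower with Ifng at -0.075 and Tnfrsf4 at -0.12, and migratory DCs against macrophages had 30 lower with Gzma at -1.30 and Nr4a1 at -0.040 (log2).

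Without doublet removal shares were 2.11% for cycling cells, 9.63% for macrophages and 1.18% for monocytes, and Cd274 in monocytes was 310 CPM. Macrophages against monocytes had 10 higher and 32 lower, and these reversed (log2): Cd101 0.29, Fcgr1 0.49, Fcgr2b 0.89, Fcgr3 0.16, Gzmc -0.44, Ifng -1.07, Klf2 -0.46, Pdcd1lg2 0.60, Spn -0.76, Tnfrsf4 -0.74 and Tnfrsf9 0.045. In the split by Pdcd1, Itgb2 was 0.14 and Prf1 -0.30.

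Under stricter filters cycling cells were 1.85%, macrophages 9.72% and 1 gene was higher in macrophages than in monocytes. With the mean over cells, Cd274 in monocytes was 425 CPM.

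Thinned to 1000 UMIs, 39.0% of activated CD8 T cells held a Pdcd1 UMI, 1 gene was higher, Itgb2 was 0.038 and Prf1 -0.13 (log2). Without thinning 86.4% held one, 5 genes were higher and 2 lower, and Fos was -0.024 (log2).

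With each population left out in turn, 8 of 126 levels and counts moved and 0 reversed, and of 1701 values of genes the naming rule took and of list medians 107 moved and 1 reversed (Ifng in migratory DCs, outside that rule, also turned lower without population 7). Pdcd1 came to 511 to 540 CPM in activated CD8 T and 75 to 102 in Tregs, Cd274 to 303 to 569 in monocytes and 364 to 430 in migratory DCs, genes higher in macrophages than monocytes to 1 to 5, and Gzma in migratory DCs to -1.88 (without population 7) to 2.73 (log2). Classes were not tested in pairs within populations, because populations without a mouse or site are no replicates of a group, and ratios within them are given as ranges. Resolution 1.6 gave no naive CD8 T class and so no comparison with it. Resolution 0.6 gave no separate monocyte, cycling, migratory DC or germinal centre B class, and so no Cd274 level or comparison of these. Tumours against lymph nodes, the antibodies and migratory DCs against type 2 conventional DCs were planned and not run. Genes under 50 UMIs over both classes could not be read at this depth.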

Other observations

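All tests in this part, the comparison of cluster 14, its values within and without populations and the finer Treg-like cells, were chosen only after the result was seen.

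Cluster 14, 620 cells led by Samd3, Cd7 and Ifitm10 that matched no marker class, had 26 of 89 measured list genes at least 2-fold higher than naive CD8 T-like cells and 1 lower, by size and not by a test. Killing and cytokine genes were higher in 8 of 10 (median log2 2.49): Gzmk was 21.4-fold (12.1 to 40.8), Fasl 20.1-fold (14.3 to 29.0), Ifng 11.6-fold (8.84 to 15.4), Ccl4 7.30-fold and Gzma 6.79-fold higher (4.19-fold without population 4). Cd44, which memory T cells carry, was 5.83-fold higher (4.96 to 7.05 within 6 populations), Pdcd1 and Cd244 7.13-fold (Pdcd1 3.18-fold without population 4), Pdcd1lg2 7.04-fold and Fcer1g 7.52-fold, while H2-DMa was 2.54-fold lower. S1pr1 (1.86-fold), Klf2 (1.83-fold), Slamf6 (1.64-fold), Cd226 (1.63-fold), Lat (1.602-fold), H2-Eb1 (1.36-fold), Vsir (1.36-fold) and H2-Ab1 (1.35-fold) were lower by less. In 6 populations with at least 20 cells of both, 16 of the 26 higher genes kept their direction in each, and with these alone 15 were still at least 2-fold higher. Cxcl10, an interferon-induced chemokine, was 8.69-fold higher in the pool but 0.314 to 7.80-fold within populations.

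Treg-like cells differed between populations in the cytotoxic protease Gzmb more than in Pdcd1. In populations 1 to 9, in order, Gzmb had 878, 35.7, 7.60, 2393, 120, 37.2, 2567, 108 and 31.4 CPM, and Pdcd1 287, 68.5, 57.7, 191, 98.4, 44.1, 127, 59.1 and 27.3. The values of Gzmb in populations 1, 4 and 7 lie apart from the other 6. The class also holds activated CD4 T-like cells, 17.4 to 53.8% of it by population at the finer clustering. In its finer Treg-like cells alone, 23 to 87 per population, Gzmb had 1048, 77.0, 8.24, 3116, 434, 27.1, 4052, 374 and 98.3 CPM, and Pdcd1 275, 27.2, 124, 177, 88.0, 72.2, 47.0, 20.0 and 57.3. In cluster 14 Isg15, induced by interferon, had 669, 29.1, 29.98, 529, 54.0, 37.0, 141, 82.0 and 99.6 CPM.

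In populations 1, 4 and 7, in order, activated CD8 T-like cells had 830, 392 and 204 CPM of Isg15 and 3003, 4798 and 1938 CPM of Gzmb, and NK-like cells had 941, 1593 and 2235 CPM of Gzmb. Cd274 had 476, 619 and 271 CPM in monocytes and 351, 368 and 181 CPM in macrophages. Ifng, which raises PD-L1, had 671, 1132 and 732 CPM in activated CD8 T-like cells. Which mouse each population comes from is not given in the sources used here, so none of these values was set against an antibody.

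Cluster 10, 479 unnamed cells led by Tmem176a, Pltp and Tmem176b, had macrophage markers at a mean log2 of 1.81, under the limit for a name. Its cells numbered 204 in population 1, 225 in population 4, 32 in population 7 and at most 1 in each other population. Cluster 16, 78 B cell-like cells led by Pkib, Kmo, Hsh2d, Slfn5 and Oas2, held 48 cells of population 9, 16 of population 2, 8 of population 3, 3 of population 5, 2 of population 8, 1 of population 6 and 0 of populations 1, 4 and 7.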
